A study of Danio rerio with 7 samples.

How the data were processed

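Whole zebrafish of the Tübingen strain were sampled at 21 days, with 4 wild-type libraries and 3 libraries from homozygous carriers of the rabl3-TR41 allele, and polyA RNA was sequenced on an Illumina HiSeq. The labels do not state whether a library came from a single fish or from a pool, so replicates are not stated to be separate animals, and p-values measure only the spread between libraries.

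The submitters' processing notes name STAR 2.3, HTSeq 0.6.0 and DESeq2 with no version, and the Zv9 genome build, without saying which tool made which value. The annotation release, the strand setting and any filter were not given in the sources used here. Since the strand setting is unknown, reads of overlapping or antisense genes cannot be separated. The deposited table holds raw counts per gene and library, and the smallest total of a listed gene was 34 reads. Per the labels, its normalized columns hold signal, which equals the count divided by 1 size factor per library. The log2 fold changes deposited by the authors are mutant over wild type and shrunken, with a slope of 0.336 across all 27581 genes on the log2 ratio of the normalized means. The shrinkage differed between genes. For rabl3 the deposited value was -1.36 against -1.47 in the edgeR fit described below, and for 5S_rRNA on chromosome 10 it was -1.82 against -3.81. The score deposited by the authors is the Wald statistic. The deposited table gives each p-value and adjusted p-value of the authors' test, with 7206 adjusted values not given.

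All fits started from the raw counts. Of 27581 genes, 27234 passed filterByExpr of edgeR 4.0.16 with a minimum count of 10, run in R 4.3.3. Counts were scaled by TMM, fitted by glmQLFit without robust estimation and tested by glmQLFTest with group as the single term, all 7 libraries together. P-values were adjusted by the Benjamini-Hochberg method (BH), and a gene was called at an adjusted p below 0.05. Expression is given as TMM-scaled CPM, read counts over the scaled library total, as mean ± SD. Library totals ran from 60095254 to 67255313 counts. For a gene with 0 counts in a whole group, the fold was bounded with 3 counts over the group, which covers counting error only, since reads without molecular identifiers are not independent molecules.

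The test, the comparisons, the rule for named genes, the gene lists and the first set of alternatives were chosen before the data were examined. The rule named rabl3, the 12 largest changes in each direction among called genes with a mean of at least 100 normalized counts, groups that did not overlap and a descriptive symbol, and from each list up to 4 called members or, where none was called, 2 members with the largest change among those with a mean of at least 100 normalized counts. Other genes named in the text were chosen after their values were seen.

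Of the 35 gene lists, 34 could be tested, and the mitochondrial genome list had 0 genes in the table. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, adjusted over the lists. The lists were exocrine pancreas, endocrine islets, hepatocytes, enterocytes, RAS-MAPK output, KRAS-induced genes, RAS isoforms and prenylation, cholesterol synthesis, fatty acid synthesis and storage, glycolysis, nuclear genes of the respiratory chain, cytosolic ribosomal proteins, cell cycle, p53 targets, unfolded protein response, heat shock, fast skeletal muscle, slow and cardiac muscle, cartilage and bone, epidermis, lens, photoreceptors, nervous system, erythrocytes, neutrophils and macrophages, lymphocytes, acute inflammation, interferon response, complement, circadian clock, growth axis, fasting and catabolism, germ cells and gonad, and extracellular matrix and fibrosis. Members were matched by symbol in the deposited table or in a gene name table that held 19330 of the 27581 identifiers (70.1%). The matching of synonyms was corrected, and 3 wrongly matched genes were removed, after list results had been seen. The KRAS-induced list was written from memory of a published human collection.

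Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, robust estimation, a block for the replicate number, each library left out in turn, and other thresholds. A limma fit with estimated sample quality weights and matching of the KRAS-induced list by human ortholog were added after seeing the data. A pseudocount alternative did not apply, since the test ran on counts. The called genes on the chromosome of rabl3 were compared with the other chromosomes by Fisher's exact test, two-sided. On counts simulated for 4 against 3 libraries, edgeR recovered 84% of genes changed 2-fold and 16% of those changed 1.5-fold, with 3.87% false among its calls. DESeq2 recovered 92% and 48% with 21.0% false. Changes were planted in 50 genes per fold among 27234, only in genes with a mean of at least 1 CPM. No simulated library was set apart as mutant replicate 3 was, so these shares need not hold for the real libraries. Random lists of the fixed sizes gave 0 calls among 34, and a list shifted by -0.3 on the log2 scale was recovered. The simulated genes were drawn independently, whereas the estimated correlation of the real cholesterol synthesis list was 0.817. These random lists therefore cannot tell how often the preset correlation gives false calls on the real lists.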

Results

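RNA of whole 21-day zebrafish was counted in 4 wild-type libraries and 3 libraries from homozygous rabl3-TR41 mutants. Total counts were 63651551, 62621553, 60095254 and 61008577 in wild-type replicates 1 to 4 and 67240380, 67255313 and 62749484 in mutant replicates 1 to 3. The comparison of mutants with wild type asks which transcripts differ when RABL3, a RAS-superfamily small GTPase that the study connects to KRAS prenylation, is altered.

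The rabl3 transcript itself was lower in every mutant library. It fell from 5.98 ± 0.33 CPM (counts scaled by library total; SD, n = 4) to 2.16 ± 0.14 (SD, n = 3), which is 36.1% of the wild-type mean, from raw counts of 357 to 397 in wild type and 135 to 150 in mutants. The gene (ENSDARG00000040959) lies on chromosome 9 of Zv9 at 33682384 to 33685727. Its log2 fold change was -1.47 (SE 0.11), with an adjusted p of 0.00466 by edgeR quasi-likelihood and BH. The one-sided exact permutation p over the 35 splits was 0.0286, the smallest they can give. Doubling it gave a two-sided value of 0.0571, which is not a count of splits in both directions. With the replicate number as a block, which the values gave no reason to pair, the log2 fold change was -1.43 and the adjusted p 0.216.

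**Figure D1:**
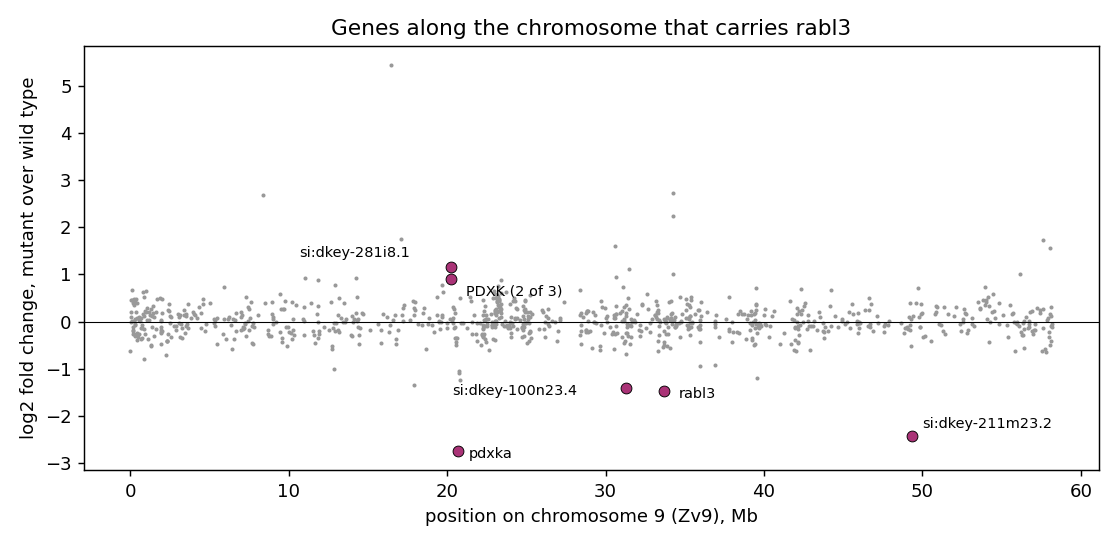
Log2 fold change, mutant over wild type (y axis), against position on chromosome 9 of Zv9 in Mb (x axis) for genes with a mean of at least 20 normalized counts. The 6 called genes are coloured and named.

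Across all genes, 23 changed in mutants, of which 9 rose and 14 fell. Among those that rose were genes of nutrient uptake and glucose release. They included slc6a19a, a transporter of neutral amino acids, and g6pca.2, a glucose-6-phosphatase of gluconeogenesis. An aminopeptidase gene, anpepa in the deposited table and anpeplb in the gene name table, also rose. Those that fell included elovl6, an elongase of fatty acids, both type I collagen genes col1a1a and col1a2, and the osteocalcin gene bglap, listed as si:ch1073-504d15.2. The slc6a19a transcript rose from 1.53 ± 0.36 to 9.74 ± 3.74 CPM (SD, n = 4 and n = 3), a log2 fold change of 2.67 with an adjusted p of 0.0396 by edgeR quasi-likelihood and BH. The elovl6 transcript fell from 59.3 ± 5.77 to 16.8 ± 4.26 CPM, a log2 fold change of -1.82 with an adjusted p of 0.0132. The calls of anpepa, g6pca.2, col1a1a, col1a2 and bglap were among 13 of the 23 that held in 1 of the 7 fits with a library left out, the one without mutant replicate 3. Without mutant replicate 1, for example, the adjusted p was 0.202 for anpepa, 0.0998 for g6pca.2, and 0.213 for col1a1a, col1a2 and bglap. The slc6a19a call held in 2 of these fits, without mutant replicates 2 and 3, and the elovl6 call in 3, without wild-type replicates 1 and 3 and mutant replicate 3.

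Other genes that rose were entpd8, an ectonucleotidase (log2 fold change 1.43), GLS2 (2 of 2), a glutaminase (1.02), PDXK (2 of 3), a pyridoxal kinase (0.90), si:dkey-281i8.1 (1.15), zgc:175280 (0.87) and CABZ01073641.1 (0.68). The g6pca.2 transcript rose from 140 ± 10.2 to 259 ± 40.4 CPM, and anpepa from 30.9 ± 2.63 to 50.3 ± 1.3. Among genes that fell, gpib, a glucose-6-phosphate isomerase, went from 63.3 ± 9.05 to 32.1 ± 2.68 CPM, and MYOZ3 (1 of 2), related to a sarcomere protein gene, had a log2 fold change of -1.46. The pyridoxal kinase gene pdxka had a log2 fold change of -2.74, si:dkey-211m23.2 one of -2.42 and si:dkey-100n23.4 one of -1.41. All 3 lie on chromosome 9 with rabl3, as do PDXK (2 of 3) and si:dkey-281i8.1. The gene si:dkey-258f14.4 had 37 to 82 counts in the wild-type libraries and 0 in every mutant library, so it was at least 58.9-fold lower. Of the fits with 1 library left out, only the one without mutant replicate 3 kept the call of si:dkey-258f14.4. The same held for the calls of entpd8, GLS2 (2 of 2), PDXK (2 of 3), zgc:175280, CABZ01073641.1, gpib and MYOZ3 (1 of 2). Counts at the noncoding RNase_MRP gene (log2 fold change -1.69) and a pair of 5S_rRNA genes (-3.09 and -3.81) were also lower. Since polyA RNA was sequenced and the strand setting is unknown, reads of overlapping genes cannot be separated from these counts. A fall of these noncoding RNAs themselves was therefore not shown. The 5S_rRNA family had 502 tested genes, of which 238 lay above and 264 below 0, and reads of such near-identical copies cannot be placed with certainty.

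**Figure D2:**
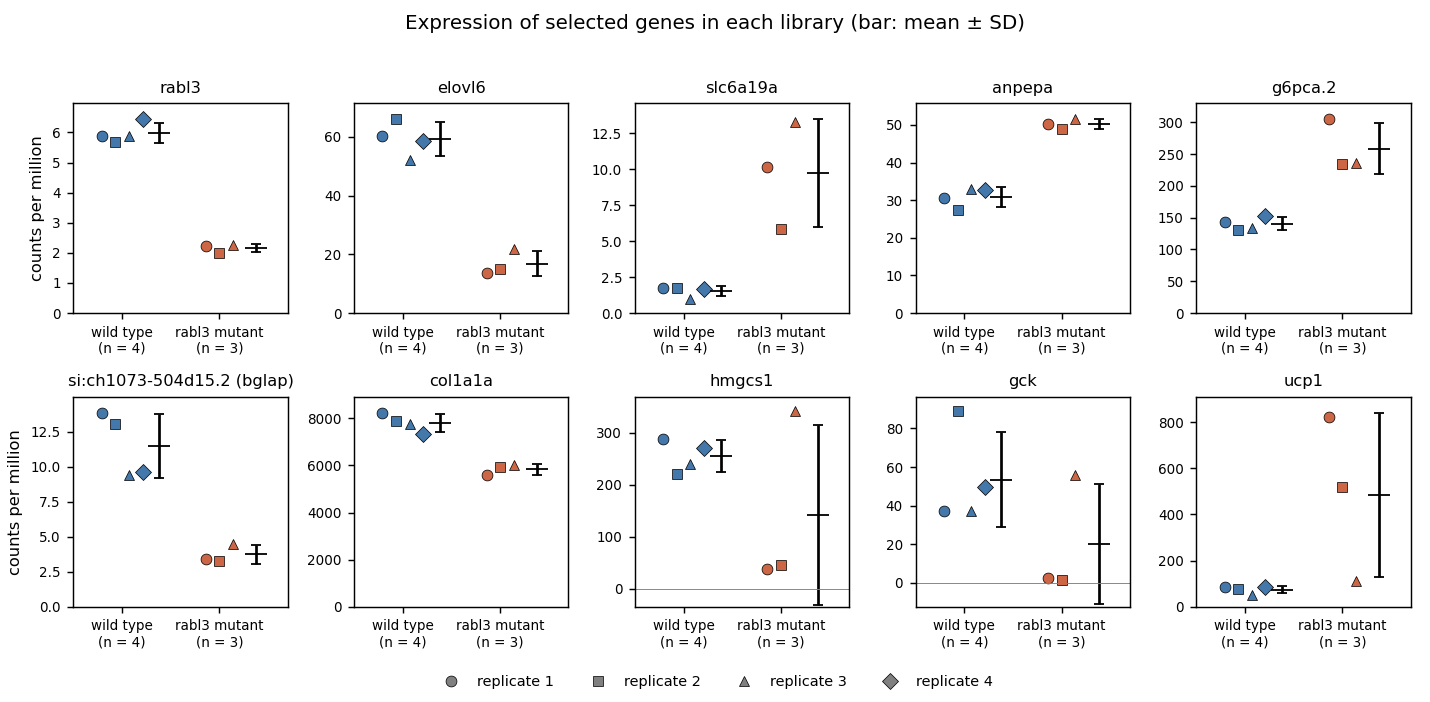
TMM-scaled CPM (y axis, linear) of 10 genes in the 4 wild-type and 3 mutant libraries, with the mean and SD beside each group. The first 7 genes were called; hmgcs1, gck and ucp1 were not, and mutant replicate 3 lies apart from the other mutant libraries in them.

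Each of the 23 genes had groups that did not overlap, as did 3052 of all tested genes (11.2%, against 5.71% by chance). At an unadjusted p below 0.05 there were 3238 genes, where a uniform spread of p-values gives 1362, and other groupings of the 7 libraries reached up to 4257. The number of called genes depended on single libraries: it was 5, 8, 7, 6 and 13 without wild-type replicates 2, 3 and 4 and mutant replicates 1 and 2, 19 (4 of them higher) without wild-type replicate 1, and 2489 without mutant replicate 3. DESeq2 called 564 genes, and the fit with a replicate block called 0 by edgeR, with 2309 at an unadjusted p below 0.05.

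**Figure D3:**
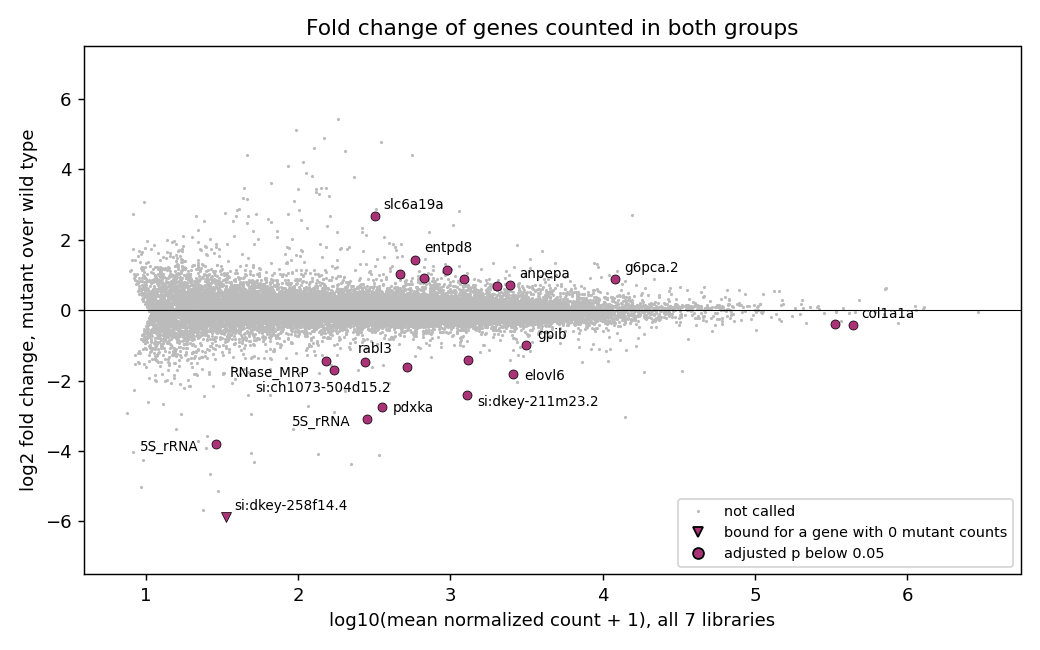
Log2 fold change, mutant over wild type (y axis), against log10 of the mean normalized count plus 1 over all 7 libraries (x axis). The 23 called genes are coloured, with si:dkey-258f14.4 as a triangle at its bound, and the other 10 of the 11 genes with 0 counts throughout a group are not drawn.

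Among the gene lists, the medians of exocrine pancreas and lens genes lay above 0, and those of cartilage and bone genes below 0, in each of the 3 mutant libraries, beyond every wild-type library. The same held for p53 targets, ribosomal protein and circadian clock genes, which lay above 0, and for cell cycle genes, which lay below 0. The margin was narrow for exocrine pancreas (0.384 in mutant replicate 3 against 0.360 in wild-type replicate 1) and cell cycle (-0.0925 in mutant replicate 3 against -0.0922 in wild-type replicate 4). Cholesterol synthesis genes lay lower in mutant replicates 1 and 2 and not in mutant replicate 3. By camera with the preset correlation 24 of 34 lists passed, 14 higher and 10 lower, while with an estimated correlation 0 passed, and 0 passed fry's test of 1 direction, its lowest adjusted p being 0.0552. Fry's mixed test, which asks whether members change in either direction, passed for 21 lists. Left-out libraries gave 16, 22, 23 and 22 lists with the preset correlation without wild-type replicates 1 to 4, and 20, 20 and 22 without mutant replicates 1 to 3. The changes below are therefore stated with the adjusted p of both camera tests.

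Digestive enzyme genes of the exocrine pancreas lay higher, with a median log2 fold change of 0.51 over 21 genes (camera adjusted p = 8.0e-11; adjusted p = 0.316 with an estimated correlation). Adjusted over the list alone 13 were higher and 2 lower, and 0 passed over all genes. The amylase gene amy2a had a log2 fold change of 0.99, and the elastase gene ela2l one of -3.03, with 34.7 CPM in wild-type replicate 1, 317 to 664 in the other wild-type libraries and 41.6 to 44.2 in mutants. Genes of enterocytes had a median of 0.28 over 29 genes (camera adjusted p = 1.7e-07; adjusted p = 0.316 with an estimated correlation). The list's median was 0.22 and 0.018 in mutant replicates 1 and 2 and 0.51 in mutant replicate 3, and it was 0.10 without that library (camera adjusted p = 0.00118; adjusted p = 0.487 with an estimated correlation). Of these genes, anpepa was called over all genes, and 6 were higher adjusted over the list alone, among them the peptide transporter slc15a1b (1.45) and anpepb (1.11). Endocrine islet genes had a median of 0.23 over 18 genes (camera adjusted p = 0.0136; adjusted p = 0.574 with an estimated correlation), with log2 fold changes of 0.39 for pcsk1 and 0.35 for pcsk2, and 0 passed adjusted over the list alone. This camera call ended without wild-type replicate 1 (adjusted p = 0.101), mutant replicate 1 (0.0659) or mutant replicate 3 (0.117). Hepatocyte genes had a median of 0.13 over 30 genes (camera adjusted p = 0.00221; adjusted p = 0.574 with an estimated correlation), and tdo2a, a tryptophan dioxygenase (0.63), was the 1 gene higher adjusted over the list alone. Without mutant replicate 1 this camera call ended (adjusted p = 0.0783). Without mutant replicate 3, 5 hepatocyte genes were higher and 1 lower adjusted over the list alone.

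Cholesterol synthesis genes lay lower, with a median of -0.62 and 23 of 25 genes below 0 (camera adjusted p = 3.6e-07; adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 0 passed, or 20 lower without mutant replicate 3, and lss (-1.19) and ebp (-1.0) also missed the threshold over all genes. The list's median against the wild-type mean was -1.36 and -1.42 in mutant replicates 1 and 2 and 0.24 in mutant replicate 3. Genes of fatty acid synthesis and storage had a median of -0.10 over 23 genes (camera adjusted p = 0.0136; adjusted p = 0.574 with an estimated correlation), with 3 higher and 3 lower adjusted over the list alone and elovl6 called over all genes. This list's medians were -0.365 and -0.403 in mutant replicates 1 and 2 and 0.205 in mutant replicate 3, and without that library the median was -0.415, with 9 members called lower and 2 higher (camera adjusted p = 2.0e-06; adjusted p = 0.12 with an estimated correlation). Its camera call ended without wild-type replicate 1 (adjusted p = 0.0729), mutant replicate 1 (0.0783) or mutant replicate 2 (0.391, with a median of 0.032). The lipid droplet genes went apart in value, with -2.88 for plin1 and 0.94 for plin2. Glycolysis genes had 1 called member, gpib, and no shift as a list (camera adjusted p = 0.981).

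Genes of fasting and catabolism had a median of 0.30 over 49 genes (camera adjusted p = 5.2e-09; adjusted p = 0.316 with an estimated correlation). The gene g6pca.2 was called over all genes, and adjusted over the list alone 13 were higher and 3 lower, among them pck1 of gluconeogenesis (1.33), the glucocorticoid-responsive klf9 (1.22) and the muscle ubiquitin ligase fbxo32 (1.80, with 18.7 and 13.5 CPM in mutant replicates 1 and 2 and 2.65 in mutant replicate 3, against 2.97 to 4.29 in wild type). The list's median was 0.45 and 0.33 in mutant replicates 1 and 2 and 0.01 in mutant replicate 3. Growth axis genes had a median of 0.05 over 28 genes (camera adjusted p = 0.0401; adjusted p = 0.379 with an estimated correlation), with 2 higher adjusted over the list alone. The genes igfbp1a and igfbp1b, named for the size of their change, had log2 fold changes of 0.94 and 2.12. Neither was called over all genes (adjusted p 0.221 and 0.274 by edgeR quasi-likelihood and BH), and igfbp1b was not among the 2 passing over the list alone. The igfbp1b transcript stood at 11.6 and 10.7 CPM in mutant replicates 1 and 2 and at 1.33 in mutant replicate 3, below the wild-type mean of 1.81. The growth axis call ended without wild-type replicate 1, 3 or 4 (adjusted p = 0.0904, 0.0523 and 0.083) or mutant replicate 1 or 2 (0.264 and 0.0679). Without mutant replicate 3 the median was 0.0944, with 5 members called higher and a fry adjusted p of 0.00678 (camera adjusted p = 0.00108; adjusted p = 0.102 with an estimated correlation). Circadian clock genes had a median of 0.16 over 38 genes (camera adjusted p = 3.1e-06; adjusted p = 0.316 with an estimated correlation), with 7 higher adjusted over the list alone, among them dbpb (0.94) and nr1d1 (0.86), and 13 higher and 1 lower without mutant replicate 3.

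Cartilage and bone genes lay lower, with a median of -0.34 over 30 genes (camera adjusted p = 8.0e-11; adjusted p = 0.316 with an estimated correlation). The genes si:ch1073-504d15.2 (bglap), col1a1a and col1a2 fell over all genes, and adjusted over the list alone 13 were lower and 1 higher. The bglap transcript fell from 11.5 ± 2.29 to 3.73 ± 0.68 CPM, and col1a1a from 7801 ± 384 to 5841 ± 229. Extracellular matrix genes had a median of -0.03 over 32 genes (camera adjusted p = 0.045; adjusted p = 0.653 with an estimated correlation), with 6 lower adjusted over the list alone, among them postna (-1.02), and with the same 2 collagens called. This camera call ended without wild-type replicate 1 or 2 (adjusted p = 0.293 and 0.0893) or mutant replicate 1, 2 or 3 (0.05002, 0.0629 and 0.223). Fast skeletal muscle genes had a median of -0.06 over 33 genes (camera adjusted p = 0.045; adjusted p = 0.614 with an estimated correlation), a call that ended without wild-type replicate 1 (adjusted p = 0.171) or mutant replicate 3 (0.61), and slow and cardiac muscle genes did not pass (camera adjusted p = 0.981), with smyd1b at -0.49 and myh6 at 0.59.

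Cell cycle genes lay lower, with a median of -0.23 over 34 genes (camera adjusted p = 8.4e-11; adjusted p = 0.344 with an estimated correlation), and 2 were lower adjusted over the list alone, one of them the mitotic kinesin kif23 (-0.40). Its medians were -0.334 and -0.371 in mutant replicates 1 and 2 and -0.0925 in mutant replicate 3, and without that library 23 genes were lower adjusted over the list alone. Heat shock genes had a median of -0.23 over 24 genes (camera adjusted p = 0.00025; adjusted p = 0.574 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone. The hsp90aa1.1 gene had a log2 fold change of -0.68 and was not called. The heat shock medians were -0.62 and -0.48 in mutant replicates 1 and 2 and 0.15 in mutant replicate 3. Without that library 2 heat shock genes were higher and 14 lower adjusted over the list alone. Nuclear genes of the respiratory chain had a median of -0.14 over 82 genes (camera adjusted p = 2.2e-08; adjusted p = 0.574 with an estimated correlation), and the 1 gene lower adjusted over the list alone, ndufv3 (-0.50), lies on chromosome 9. The medians of that list were -0.144 and -0.184 in mutant replicates 1 and 2 and -0.0331 in mutant replicate 3. Without that library 32 were lower and 1 higher adjusted over the list alone, 10 were called lower over all genes and the fry adjusted p was 0.0161 (camera adjusted p = 1.4e-07; adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes had a median of 0.08 over 85 genes (camera adjusted p = 3.7e-05; adjusted p = 0.584 with an estimated correlation), with RPS27L (0.53) higher adjusted over the list alone. The p53 targets had a median of 0.22 over 20 genes (camera adjusted p = 5.6e-06; adjusted p = 0.316 with an estimated correlation), with 5 higher adjusted over the list alone, RPS27L again and mdm2 (0.36) among them, and 11 higher without mutant replicate 3. Genes of the unfolded protein response did not pass (median 0.05, camera adjusted p = 0.418; 0.0497 and 0.0154 without mutant replicates 1 and 2, where adjusted p = 0.705 and 0.756 with an estimated correlation), although 4 were higher adjusted over the list alone, among them ddit3 (0.60). Without mutant replicate 3 that list turned to a median of -0.21 (camera adjusted p = 0.000387; adjusted p = 0.487 with an estimated correlation).

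Lens genes lay higher, with a median of 0.27 over 39 genes (camera adjusted p = 8.0e-11; adjusted p = 0.316 with an estimated correlation) and 18 higher adjusted over the list alone, among them the crystallin gene crygm2d1 (0.60). The list held 16 genes on chromosome 9, with a median of 0.32, and 23 on others, with a median of 0.24. Nervous system genes had a median of 0.15 over 31 genes (camera adjusted p = 0.0273; adjusted p = 0.653 with an estimated correlation), with gfap at 0.41 and 0 past the test adjusted over the list alone, and the call ended without wild-type replicate 1 (adjusted p = 0.589) or mutant replicate 2 (0.348). Photoreceptor genes (camera adjusted p = 0.605; 0.0243 without mutant replicate 1, where adjusted p = 0.694 with an estimated correlation) and epidermis genes (camera adjusted p = 0.366) did not pass.

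Erythrocyte genes had a median of 0.15 over 29 genes and a mean of -0.12, which differ in sign (camera adjusted p = 0.00382, direction higher; adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 8 were higher, among them the globin gene hbaa1 (0.63), and 2 were lower, the embryonic globin genes hbz (-1.74) and hbbe2 (-1.75). Both split within wild type: hbz stood at 156 CPM in wild-type replicate 1 and at 845 to 1062 in the others, against 201 to 260 in mutants, and hbbe2 at 88.4 and 458 to 593, against 104 to 148 in mutants. Without wild-type replicate 1 the direction of this camera test turned, with a median of 0.14 and an adjusted p of 0.0729. Lymphocyte genes had a median of -0.07 over 37 genes (camera adjusted p = 0.0282; adjusted p = 0.574 with an estimated correlation), with il2rb at -0.59 and 0 past the test adjusted over the list alone. This camera call ended without wild-type replicate 2 (adjusted p = 0.122) or mutant replicate 3 (0.572). Complement genes had a median of 0.17 over 29 genes (camera adjusted p = 0.0392; adjusted p = 0.653 with an estimated correlation), and 0 passed adjusted over the list alone. The call ended without wild-type replicate 1, 3 or 4 (adjusted p = 0.117, 0.0587 and 0.242) or mutant replicate 1 (0.769). Its medians were 0.445 and 0.104 in mutant replicates 1 and 2 and -0.0999 in mutant replicate 3, and without that library the median was 0.26, with 6 members called higher and 1 lower (camera adjusted p = 0.000823; adjusted p = 0.562 with an estimated correlation). Interferon response genes did not pass (median 0.05 over 40 genes, camera adjusted p = 0.0867; 0.0312 without wild-type replicate 3 and 0.048 without mutant replicate 3, where adjusted p = 0.576 and 0.562 with an estimated correlation), with 5 higher adjusted over the list alone, among them isg15 (1.5). Without mutant replicate 3, 8 interferon response genes were higher adjusted over the list alone, and 6 were called higher over all genes. Neutrophil and macrophage genes (camera adjusted p = 0.435; 0.00174 without mutant replicate 3, or 0.102 with an estimated correlation) and acute inflammation genes (camera adjusted p = 0.605) did not pass, with lyz at 0.70 and il1b at -0.99.

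The lists closest to the study's question had medians between -0.13 and 0.03. Genes of RAS-MAPK output had a median of 0.03 over 31 genes (camera adjusted p = 0.253), with phlda1 at -0.60 and fos at 0.43, and 0 members passed adjusted over the list alone. Fry's mixed test passed for this list (adjusted p = 0.00366) and for KRAS-induced genes (adjusted p = 0.00621), while its test of 1 direction did not (adjusted p = 0.381 and 0.576). KRAS-induced genes had a median of 0.01 over 209 genes (camera adjusted p = 0.598), and 0 members passed adjusted over the list alone. Genes of RAS isoforms and prenylation had a median of -0.13 over 18 genes (camera adjusted p = 0.0094; adjusted p = 0.574 with an estimated correlation), with 0 past the test adjusted over the list alone. Its medians were -0.217 and -0.238 in mutant replicates 1 and 2 and 0.0742 in mutant replicate 3. Without mutant replicate 3 the median was -0.21, with 4 members called lower over all genes, 6 lower adjusted over the list alone and a fry adjusted p of 0.00678 (camera adjusted p = 0.000163; adjusted p = 0.186 with an estimated correlation). Without mutant replicate 2 the camera call ended (adjusted p = 0.0978). The KRAS-induced list had 0 members called over all genes, and 8 higher and 5 lower without mutant replicate 3. The kras transcript had a log2 fold change of -0.28 (SE 0.10, adjusted p 0.375 by edgeR quasi-likelihood and BH), and fdps, a farnesyl diphosphate synthase shared with sterol synthesis, one of -0.74 (SE 0.41).

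Germ cell genes had a median of 1.1 over 36 genes (camera adjusted p = 8.1e-06; adjusted p = 0.574 with an estimated correlation). Without mutant replicate 3 the median was 0.26 and the camera call ended (adjusted p = 0.292). The piRNA-pathway gene piwil2 (1.15) was the 1 gene higher adjusted over the list alone. The summed level of the list was 58 to 70 CPM in the other 6 libraries and 213 in mutant replicate 3, and the egg coat genes listed as zp3.2 had log2 fold changes of 4.89 and 4.60 that came from that library.

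**Figure D4:**
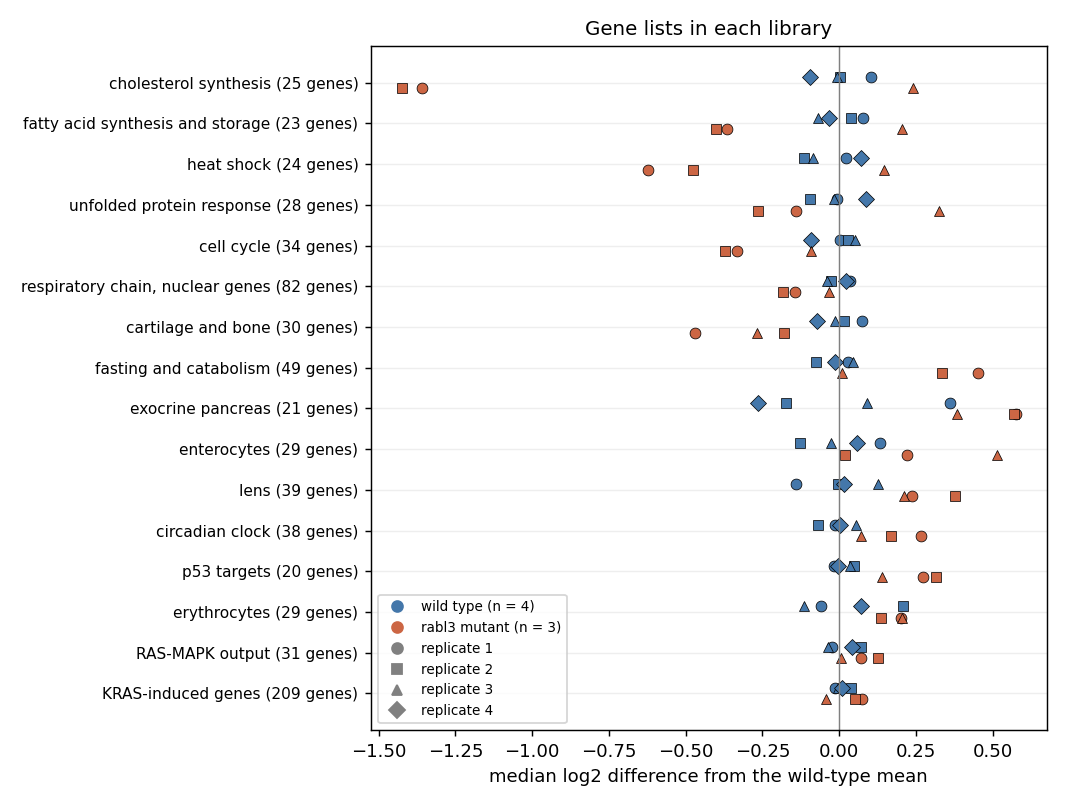
Median log2 difference from the wild-type mean (x axis) of the genes of 16 lists, for each wild-type and mutant library. Cholesterol synthesis lies at -1.36 and -1.42 in mutant replicates 1 and 2 and at 0.24 in mutant replicate 3.

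The authors' deposited table holds 640 genes at an adjusted p below 0.05, 391 higher and 249 lower. All 640 had the same direction in the edgeR fit, which used the same counts, so this is no independent support. Among these 640 were 21 of the 23 genes called here. The called genes si:dkey-258f14.4 and 5S_rRNA on chromosome 10 had no adjusted p in the deposited table. The number shared was 532 with DESeq2 and 464 with sample quality weights, and 0 with the replicate block. It was 11, 5, 7 and 7 without wild-type replicates 1 to 4, and 5, 9 and 481 without mutant replicates 1 to 3.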

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

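Among the tests in this part, those of mutant replicate 3 and the splits at an unadjusted p were chosen after the results were seen, and the other counts over splits were fixed beforehand. Of 105 values tested in the 4 wild-type libraries, 6 had 1 library far from the other 3, where chance gives 5.25. In slc6a19a wild-type replicate 3 had 1.0 CPM against 1.67 to 1.73. In ambpl wild-type replicate 2 had 90.2 CPM against 50.6 to 52.9. In ndufv3 wild-type replicate 4 had 24.3 CPM against 25.8 to 25.9. In RPS27L wild-type replicate 1 had 26.4 CPM against 31.2 to 32.0. In zgc:112320 wild-type replicate 3 had 3.20 CPM against 2.25 to 2.37. In gad1b wild-type replicate 1 had 25.4 CPM against 39.6 to 41.7.

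The real grouping called 23 genes. Among the 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many, the highest other being 8. That share, 0.0286, is the smallest that 35 splits can give, so it lies below 0.05 but does not by itself exclude chance. For gene lists past the preset camera test, 2 of 35 splits gave as many as the real 24, the highest other also being 24, so chance cannot be excluded for that count. For genes at an unadjusted p below 0.05, 3 of 35 splits gave at least the real 3238, so chance cannot be excluded there either. The highest other, 4257, set mutant replicates 1 and 2 and wild-type replicate 2 against the rest.

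Mutant replicate 3 stood apart from the other mutant libraries, and 2489 genes were called without it. The library was not wild-type RNA by its rabl3 level, 2.25 CPM against a lowest wild-type value of 5.69. RNA from oocytes added to that library stays open: the fasting list lay -0.24 log2 units from the mean of the other mutants (SE 0.14), within 2 standard errors. A second test, run after that result was seen, put the 871 genes called higher without the library (of 873, those tested in both fits) at -0.46 (SE 0.02), but those genes were chosen for being high in the other mutants and so decide nothing. A different feeding or metabolic state may also have set this library apart, since its cholesterol list lay 1.59 log2 units higher (SE 0.19), but the fasting list was undecided only under a limit of 2 standard errors set after its value was seen (under the earlier limit of 0.1 log2 units it went with this explanation), and the design cannot separate feeding from an uneven effect of the genotype.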

How the results depend on the processing

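Among the alternatives here, sample quality weights, the shared calls under each setting and matching by human ortholog were chosen after the data were seen. DESeq2 size factors and no filter kept all 23 called genes, robust estimation kept 21, and the strict filter called 19. The 23 called genes became 564 (361 higher, 203 lower) with DESeq2, 1155 (462 higher, 693 lower) with sample quality weights, which gave mutant replicate 3 a weight of 0.285, and 0 (0 higher, 0 lower) with the replicate block. Leaving out 1 library at a time gave 5 to 2489 genes, 0 to 873 higher and 5 to 1616 lower, the fewest called without wild-type replicate 2 and the most without mutant replicate 3. Only 5 of the 23 were called in all 7 of these fits: 5S_rRNA on chromosome 6, and si:dkey-211m23.2, pdxka, si:dkey-100n23.4 and rabl3, all on chromosome 9. A 2-fold minimum left 15, an adjusted p below 0.01 left 6 and one below 0.1 gave 90. Genes shared with the authors' deposited table went from 21 to 532 with DESeq2, 464 with sample quality weights, 0 with the replicate block, and 5 to 481 without 1 library. The rabl3 log2 fold change with the replicate block was -1.43 (adjusted p 0.216). Lists past the test numbered 24 with the preset correlation, 0 with an estimated correlation and 0 with fry, and without mutant replicate 3 they numbered 22, 1 and 13. The camera direction of the erythrocyte list turned without wild-type replicate 1 (median 0.14; 0.064 to 0.174 over the left-out libraries) and the unfolded protein response list without mutant replicate 3 (median -0.21; up to 0.133 without the other libraries). The replicate block removes residual degrees of freedom by its construction, and for the other changes the cause was not tested. With no calls under that block, the chromosome comparison gave no value there. Library totals were 60095254 to 63651551 counts in wild type and 62749484 to 67255313 in mutants, with mutant replicates 1 and 2 above every wild-type library.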

Other observations

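The tests of chromosome 9 against the others were fixed beforehand, while the reading of linked variants, the summed pyridoxal kinase counts and the genes and tests without mutant replicate 3 and the chromosome comparison under other settings were chosen after the results were seen. Without mutant replicate 3 the edgeR fit gave a lower sterol program: 18 of 25 cholesterol synthesis genes were called lower over all genes, among them hmgcs1 (log2 fold change -2.61) and lss (-2.51). By camera with an estimated correlation this list alone of the 34 passed there, with an adjusted p of 0.0334. Fasting genes had 21 called higher and 3 lower, with ucp1 at 3.18 and fbxo32 at 2.27, and heat shock genes had 11 called lower and 1 higher. By fry 13 of the 34 lists passed there. The glucokinase gene gck had a log2 fold change of -4.81 and the brush border genes slc15a1b, ace2 and slc13a2 had 1.64, 1.49 and 1.56. Since this subset of 2 mutant libraries was singled out after the values were seen, these counts do not stand for the genotype as a whole. In the held-out mutant replicate 3, 767 of the 2487 of these genes tested in both fits (30.8%) lay beyond every wild-type library on the same side. The genes were called against the same wild-type libraries, which raises this share, so it has no known value for no change and shows no repeat of the calls. All 23 genes called with 7 libraries were among those called without it. The share beyond wild type was 42.7% on chromosome 9 and 30.1% on the others (odds ratio 1.73, p = 0.00205 by Fisher's exact test, two-sided). That test takes genes as independent, while all of them were measured in a single library, mutant replicate 3. Its p-value therefore does not measure the spread between libraries and decides nothing about the genotype.

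Called genes lay on chromosome 9, which carries rabl3, more often than on the others: 6 of 998 tested genes against 17 of 26236 (odds ratio 9.33, 95% interval 3.00 to 24.9, p = 0.000141 by Fisher's exact test, two-sided). This odds ratio was 105, 26.3 and 65.8 without wild-type replicates 2, 3 and 4, 52.6 without mutant replicate 1 and 1.7 without mutant replicate 3, and it was 3.14 with DESeq2, 2.07 with sample quality weights and 2.94 for the calls of the authors' deposited table. Variants inherited with the selected allele may account for part of this, since without rabl3 itself the odds ratio was 7.77 (2.24 to 22.0). Of the 5 called genes then left, si:dkey-281i8.1, PDXK (2 of 3) and pdxka lie close together, between positions 20210249 and 20690742. Fisher's test takes genes as independent, so the odds ratios of 9.33 and 7.77 rest on fewer loci than genes. The windows of 5, 10 and 20 Mb around rabl3, that gene included, gave 11.8, 6.50 and 14, and the interval at 10 Mb (0.736 to 26.7) included 1. Reads shared between the paralogs pdxka and PDXK (2 of 3) may account for that pair, since their summed counts differed by a log2 fold change of -0.0713 (SE 0.11), with 16.6 ± 1.69 CPM in wild type and 15.8 ± 1.32 in mutants. An opposite change of both genes gives the same sum, and the deposited counts cannot separate these.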
